A study of Arabidopsis thaliana with 18 samples.

How the data were processed

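Expression was measured on arrays of RNA from Col-0 Arabidopsis, dry seeds and seedlings 72 h after imbibition, as total, monosomal and polysomal RNA with 3 replicates per group. According to the labels, total and polysomal RNA were purified with TriPure reagent followed by RNeasy columns, and biotin-labelled cRNA was made with the 3' one-cycle kit. How fully this labelling covers organelle-encoded, small nuclear and small nucleolar RNAs was not tested, so their values are signals of the labelled part. The labels describe a randomized complete block layout in which each replicate was a bulk of 8 plants. The deposited values are log2 intensities after robust multi-array averaging (RMA), per the submitters' processing notes, with 1 value per gene locus and array. The version of RMA, the platform and the grouping of probes were not given in the sources used here. Sorted values of the arrays were similar but not identical, so the arrays had been scaled towards a common distribution, and the amount of RNA in a fraction was not measured. Array medians lay between 3.05 and 3.65. There are no read counts or depths on arrays, and their number limits the precision.

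The value table had 27827 rows, no repeated locus, no missing value, no detection call and no control row, and all rows were tested. Of these, 27241 were matched by locus to the RefSeq gene table of assembly TAIR10.1 and 586 were not. The table served for names and gene types, no coordinates were used, and gene length was not used here. In all, 182 rows were identical to another row on all arrays, in 88 sets. Of 92 mitochondria-encoded rows 37 were among them, 33 of these with a row of chromosome 2. Such rows were kept, and the locus they measure is uncertain. No pair of arrays had identical values.

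Sample groups were taken from the labels. A linear model with 6 group means was fitted in limma 3.58.1 under R 4.3.3, with moderated statistics and 12 residual degrees of freedom. The 12 comparisons were seedling against dry seed in each fraction, each pair of fractions within each stage, and the difference of each fraction pair between stages. A gene was called when its p, adjusted over all genes of a comparison by Benjamini and Hochberg, was under 0.05, and the count with a change of at least 2-fold was given beside it. Replicates were not paired, because the labels do not tie a replicate number to a block.

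A set of 20 gene lists with 468 measured members was fixed before the files were opened (1 further list locus, of an oil body gene, was not in the table). The lists were seed storage proteins, oil body proteins, LEA proteins, heat shock proteins, ABA synthesis and signalling, seed maturation regulators, gibberellin synthesis and signalling, cell wall loosening, photosynthesis, lipid mobilisation, cell cycle, cytosolic ribosomal proteins, translation factors, proteasome, antioxidant enzymes, seed coat and endosperm markers, root markers, shoot apex and stomatal markers, chloroplast-encoded and mitochondria-encoded genes. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with the correlation estimated from the data. Calls were also counted with p adjusted over the list alone. Genes named were the 5 largest changes in either direction among called genes, and up to 4 called members of each list with the largest change. To these were added 18 genes chosen beforehand (CRA1, OLEO1, EM6, HSP101, ABI3, ABI5, DOG1, CYP707A2, GA3OX1, EXPA2, ICL, CAB2, RBCS1A, CYCB1;1, RPS6, AT1G07920, ACT7 and UBQ10). For comparisons between groups the largest changes were taken from genes whose 3 values per group did not overlap. Overlaps of called genes were tested with Fisher's exact test, two-sided. Lists of large and small proteins were written after these lists and before their values were seen.

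The model was tested on simulated data with changes added to the dry seed polysomal arrays in 200 of 27827 genes. Of added log2 changes of 0.5, 4 of 67 (6%) were called, of changes of 1, 28 of 67 (41.8%), and of changes of 2, 61 of 66 (92.4%), with 2 false calls. A shift of 0.5 in the photosynthesis list was called at an adjusted p of 6.79e-15, and 0 of the 19 other lists were called. Simulated genes were drawn independently of each other, whereas the correlation estimated from the data was 0.17 for photosynthesis and 0.76 for storage protein genes. The simulation therefore cannot show how often the set test at the preset correlation makes false calls here.

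Alternatives tried were centring each array on its median or its 75th percentile, loess scaling between arrays, leaving out genes with the lowest means, a trend and robust variance prior, array weights, fits with only the groups of a comparison, a replicate block, fits that left out each array in turn, a stricter threshold and a required change. The set test without seedling polysomal replicate 3 was added after the data were seen. Every other alternative was listed before the data were examined.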

Results

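The data were whole-genome expression arrays from Col-0 Arabidopsis at 2 stages, dry seeds and seedlings after 72 h of imbibition. At each stage RNA was taken as total RNA, as RNA sedimenting with single ribosomes (monosomal) and as RNA on several ribosomes (polysomal). Each of the 6 groups held 3 arrays, 18 in all, and each array gave a log2 value for 27827 genes. Array medians lay between 3.05 and 3.65, the lowest single value was 0.07 and the highest 12.74. The number of arrays limits the precision. Across genes, which are not independent replicates, the correlation between replicate arrays lay between 0.957 (monosomal, seedling) and 0.990 (polysomal, dry seed). Between dry seed and seedling arrays, over all pairs of any fractions, it lay between 0.634 and 0.712. The first principal component held 78.2% of the variance and separated the stages. Values under the array medians lie near the background, so changes to or from them are compressed. Arrays had been scaled to each other, so a value gives a transcript's share of its fraction and not its amount. Group values are means ± SD of log2 values (n = 3), changes are on the log2 scale with their standard error (SE), and p was adjusted over all genes of a comparison. The set test on gene lists assumed a preset correlation between genes, and where a call was lost with an estimated correlation that p follows.

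Seed transcripts varied between replicate arrays of seedlings, most on 1 polysomal array. On the seedling polysomal arrays, the median of the 9 seed storage protein genes was 2.96, 2.39 and 6.49 for replicates 1, 2 and 3, and that of the 24 late embryogenesis abundant (LEA) genes was 3.39, 3.46 and 5.91. The photosynthesis list had medians of 10.07, 9.75 and 10.02. On the seedling monosomal arrays replicate 1 lay above the others by less, with LEA medians of 4.90, 4.06 and 3.27 and with oil body genes above the others too, while storage protein medians were 3.43, 3.39 and 3.39. The cruciferin gene CRU2 (AT1G03880) had a mean of 3.42 ± 2.71 in seedling polysomal RNA against 2.12 ± 0.18 in seedling total RNA.

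**Figure D1:**
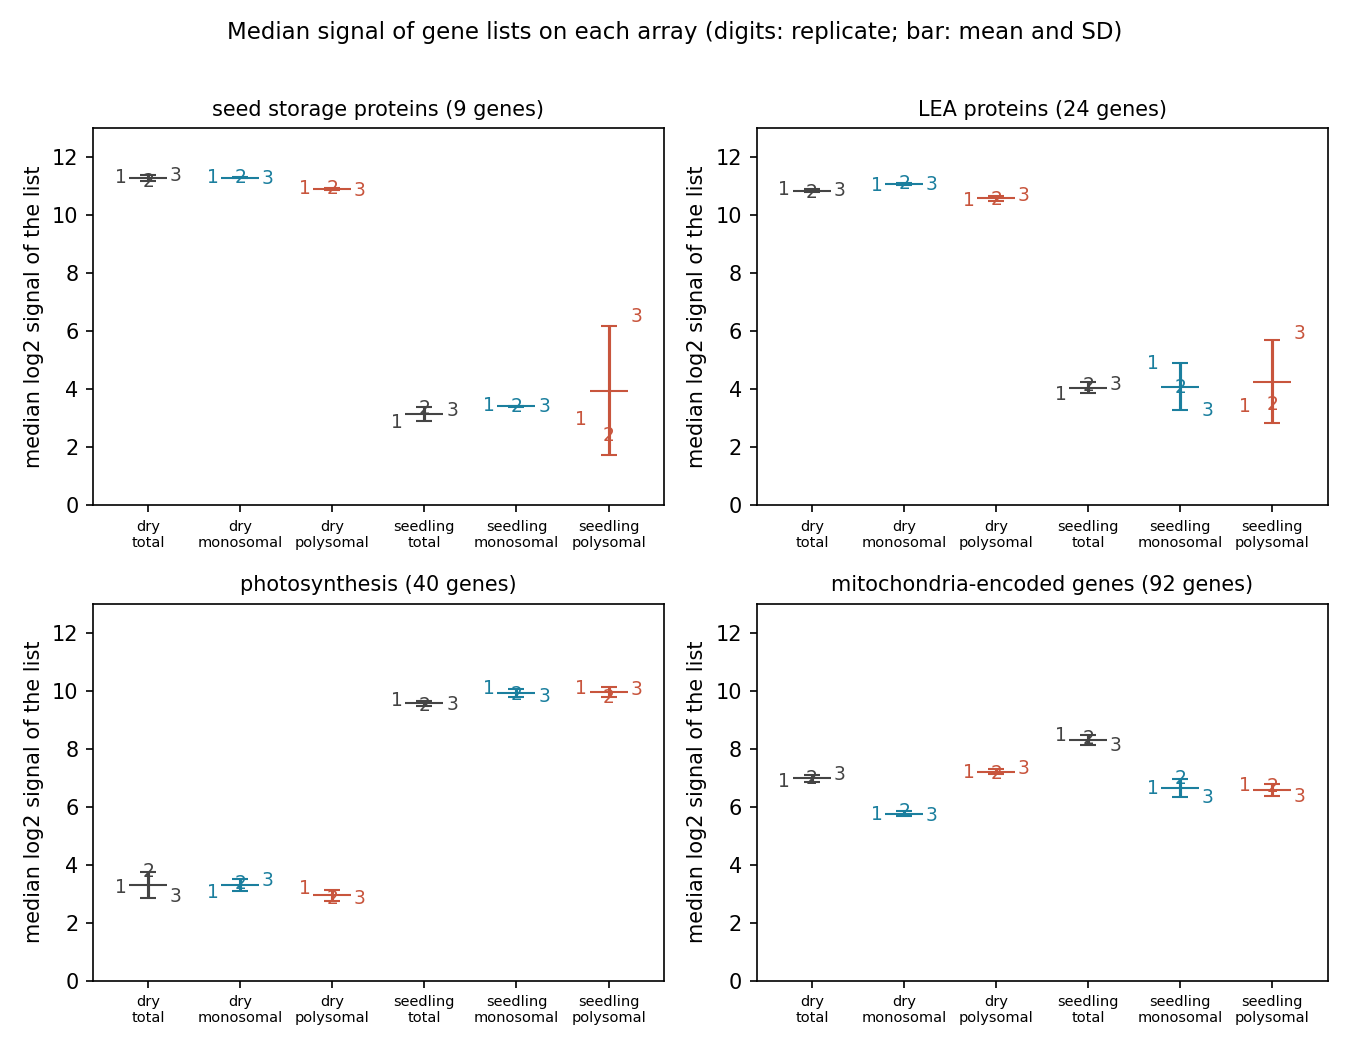
Median log2 value of 4 gene lists on each of the 18 arrays by stage and fraction, with digits for the replicate number and bars for the group mean and SD. Seed storage and LEA genes lay above 10 in all dry seed fractions and below 7 in seedlings, where polysomal replicate 3 stood apart at 6.49 and 5.91, and mitochondria-encoded genes were highest in seedling total RNA.

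Total RNA of seedlings and dry seeds was compared to ask which stored transcripts disappear and which appear during germination. Transcripts of reserves and desiccation protection were lost. All 9 storage protein genes fell, among them CRU2, from 11.51 ± 0.01 to 2.12 ± 0.18 (change −9.40, SE 0.76, adjusted p = 1.62e-09), and CRA1 (AT5G44120), another cruciferin (change −8.18, SE 0.74, adjusted p = 9.24e-09). The oleosin gene OLEO4 (AT3G27660), whose product coats oil bodies, fell from 11.37 ± 0.01 to 3.07 ± 0.32 (change −8.31, SE 0.63, adjusted p = 6.00e-10). The abscisic acid (ABA) response factor ABI5 (AT2G36270) fell from 9.77 ± 0.02 to 4.76 ± 0.23 (change −5.01, SE 0.23, adjusted p = 5.79e-13), and the dormancy gene DOG1 (AT5G45830) from 6.31 ± 0.37 to 2.85 ± 0.35 (change −3.46, SE 0.29, adjusted p = 3.16e-09). The light-harvesting gene CAB1 (AT1G29930) rose from 3.01 ± 1.26 to 10.79 ± 0.11 (change 7.78, SE 0.40, adjusted p = 1.99e-12), and GA3OX2 (AT1G80340), which makes active gibberellin, rose from 1.87 ± 0.55 to 6.26 ± 0.22 (change 4.39, SE 0.38, adjusted p = 5.78e-09). The strongest rises also held PYK10 (AT3G09260), a β-glucosidase of seedlings, with 7.79, and the gibberellin-responsive GASA4 (AT5G15230), also with 7.79. Among the deepest falls was that of AT1G05510, an oil body associated protein gene, from 11.26 ± 0.07 to 1.77 ± 0.31, a value near the background.

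By list in total RNA, all 8 oil body genes fell (median change −7.96, set test adjusted p = 1.16e-06, adjusted p = 0.114 with an estimated correlation). All storage protein genes fell (median −7.66, adjusted p = 7.18e-07, adjusted p = 0.126 with an estimated correlation). Of 24 LEA genes 23 fell (median −6.66, adjusted p = 4.95e-12, adjusted p = 0.114 with an estimated correlation). Heat shock genes fell in 18 of 21 cases with 1 rise (median −4.70, adjusted p = 7.46e-09), including HSP17.6A (AT5G12030, change −8.00). Of 27 ABA genes 17 fell and 7 rose (adjusted p = 0.00744), and of 19 seed maturation regulators 10 fell and 3 rose (adjusted p = 0.0113). All 40 photosynthesis genes rose (median 6.56, adjusted p = 3.60e-27). Rises were also seen in 12 of 14 cell wall loosening genes (13 when adjusted over the list alone; adjusted p = 3.77e-07), 19 of 24 cell cycle genes (adjusted p = 2.64e-08), 49 of 54 ribosomal protein genes (50 when adjusted over the list alone; adjusted p = 1.32e-12) and 14 of 15 chloroplast-encoded genes (adjusted p = 1.50e-08). Mitochondria-encoded genes rose in 57 of 92 cases and fell in 8 (median 1.27, adjusted p = 1.71e-07, adjusted p = 0.172 with an estimated correlation). Root markers rose in 6 of 10 cases (adjusted p = 0.0113, adjusted p = 0.146 with an estimated correlation), among them the Casparian strip gene CASP1 (AT2G36100) by 3.87. The antioxidant list held opposite changes, with the seed peroxiredoxin gene PER1 (AT1G48130) at −8.68 and the ascorbate peroxidase gene APX1 (AT1G07890) at 5.21, and its median (−0.27) and mean (−0.38) were negative while the set test pointed up (adjusted p = 0.971). The receptor genes of gibberellin moved apart, GID1B (AT3G63010) by 3.51 and GID1A (AT3G05120), which fell by 3.51. Lists without a call were lipid mobilisation (5 rises, 8 falls, adjusted p = 0.412), proteasome (5 rises, 7 falls, adjusted p = 0.959), gibberellin (7 rises, 6 falls, adjusted p = 0.637), translation factors (11 rises, 1 fall, adjusted p = 0.0629, but called higher with loess scaling at adjusted p = 0.0131), seed coat and endosperm (2 rises, 6 falls, adjusted p = 0.294), with EPR1 (AT2G27380) at −4.38, and shoot apex and stomata (4 rises, adjusted p = 0.200), with SPCH (AT5G53210) at 3.72. The median was 0.31 for the gibberellin list but −0.20 when each array was centred on its median, 0.15 but −0.35 for translation factors, and −0.04 but 0.22 with loess scaling for the proteasome.

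In limma, 8019 genes rose and 9275 fell in total RNA, 6106 and 5339 of them by at least 2-fold. The median change of all genes was −0.17, and centring arrays on their medians moved it by −0.51 and the counts to 5783 and 15017. In 66.8% of genes the value ranges of the groups did not overlap, against 10% by chance.

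Monosomal RNA of both stages was compared to ask which transcripts held with single ribosomes are exchanged during germination. CAB1 rose from 2.15 ± 0.42 to 11.22 ± 0.01 (change 9.07, SE 0.40, adjusted p = 2.39e-13), PYK10 by 8.60 (SE 0.23, adjusted p = 1.31e-15) and the germin-like gene GER3 (AT5G20630) by 8.49 (SE 0.31, adjusted p = 2.28e-14). CRU2 fell from 11.43 ± 0.11 to 2.98 ± 0.74 (change −8.46, SE 0.76, adjusted p = 8.04e-09), XTH25 (AT5G57550), a cell wall remodelling enzyme gene (change −8.86, SE 0.71, adjusted p = 1.73e-09) and AT4G11310 (change −9.12). DOG1 fell from 7.27 ± 0.05 to 2.99 ± 0.19 (change −4.28, SE 0.29, adjusted p = 1.42e-10) and ABI5 (change −5.66, SE 0.23, adjusted p = 1.16e-13). All 9 storage protein genes (median −6.74, adjusted p = 2.30e-07, adjusted p = 0.120 with an estimated correlation) fell. So did all 8 oil body genes (median −7.52, adjusted p = 2.25e-07, adjusted p = 0.0970 with an estimated correlation) and 22 of 24 LEA genes (median −6.42, adjusted p = 7.36e-14, adjusted p = 0.0970 with an estimated correlation). Heat shock genes fell in 20 of 21 cases (median −5.86, adjusted p = 3.47e-13) and ABA genes in 15 of 27 with 6 rises (adjusted p = 0.00677). Rises covered 39 of 40 photosynthesis genes (median 6.66, adjusted p = 6.58e-28), 13 of 14 cell wall loosening genes (adjusted p = 2.25e-07), 21 of 24 cell cycle genes (adjusted p = 7.98e-08), 48 of 54 ribosomal protein genes with 1 fall (adjusted p = 1.69e-12) and 13 of 15 chloroplast-encoded genes (adjusted p = 5.39e-08). Translation factor genes rose in 13 of 23 cases and fell in 3 (adjusted p = 0.0223, adjusted p = 0.122 with an estimated correlation). Root markers rose in 7 of 10 (adjusted p = 0.0112, adjusted p = 0.128 with an estimated correlation). Mitochondria-encoded genes rose in 44 of 92 and fell in 17 (adjusted p = 0.0149, adjusted p = 0.565 with an estimated correlation). The seed maturation list had a median of 0.02, which turned to −0.34 with arrays centred on their medians, against a mean of −1.09 and a set test pointing down (adjusted p = 0.0914). In all, 7447 genes rose and 6918 fell, 5378 and 4948 by at least 2-fold. The median change was 0.03, moved by −0.36 when arrays were centred on their medians (5529 rises, 10332 falls) and by 0.18 with the 75th percentile. For 53.9% of genes the groups did not overlap, against 10% by chance.

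Polysomal RNA of both stages was compared to ask which transcripts engaged by several ribosomes change. Among the largest rises were those of the aldolase gene FBA2 (AT4G38970) from 2.81 ± 0.34 to 11.18 ± 0.08 (change 8.37, SE 0.28, adjusted p = 5.74e-15) and of LHCB2.2 (AT2G05070), by 8.33 (SE 0.21, adjusted p = 3.82e-16). SYP111 (AT1G08560), the syntaxin of cell plate formation, rose from 1.85 ± 0.13 to 6.91 ± 0.15 (change 5.07, SE 0.23, adjusted p = 3.20e-13) and RPS6 (AT4G31700), a ribosomal protein gene, by 2.54 (SE 0.17, adjusted p = 8.11e-11). CRU2 fell from 11.54 ± 0.06 to 3.42 ± 2.71 (change −8.12, SE 0.76, adjusted p = 1.36e-08) and ATECP31 (AT3G22500), a LEA gene (change −8.24, SE 0.48, adjusted p = 1.22e-11). Storage protein (9 of 9, median −6.13), oil body (8 of 8, median −6.83) and LEA genes (22 of 24 with 1 rise, median −6.12) fell, at adjusted p = 1.72e-06, 1.56e-06 and 1.30e-11. These were adjusted p = 0.139, 0.119 and 0.119 with an estimated correlation. Without seedling polysomal replicate 3 these medians were −7.21, −7.84 and −6.97. Heat shock genes fell in 18 of 21 cases with 1 rise (adjusted p = 4.81e-10), ABA genes in 16 of 27 with 8 rises (adjusted p = 0.00556) and seed maturation regulators in 9 of 19 with 3 rises (adjusted p = 0.0158). All 40 photosynthesis genes (median 7.11, adjusted p = 1.65e-28), 21 of 24 cell cycle genes (median 2.84, adjusted p = 4.81e-10), 51 of 54 ribosomal protein genes (adjusted p = 1.28e-14), 11 of 14 cell wall loosening genes (adjusted p = 1.72e-06) and all 15 chloroplast-encoded genes (adjusted p = 7.07e-08) rose. Translation factor genes rose in 13 of 23 cases and fell in 2 (adjusted p = 0.0280, adjusted p = 0.143 with an estimated correlation and 0.113 with arrays centred on their medians). Root markers rose in 6 of 10 and fell in 1 (adjusted p = 0.0269, adjusted p = 0.195 with an estimated correlation and 0.0541 with loess scaling). Mitochondria-encoded genes, unlike in the other fractions, fell in 39 of 92 cases and rose in 14 (median −0.47, adjusted p = 0.0104, adjusted p = 0.443 with an estimated correlation). Isocitrate lyase (ICL, AT3G21720), of the glyoxylate cycle, rose by 0.66 (SE 0.16, adjusted p = 0.00116), but its change was −0.22 with loess scaling. Rises numbered 7436 and falls 7471, 5675 and 5455 of at least 2-fold. The median change was −0.03, moved by −0.44 with arrays centred on their medians (5582 rises, 12145 falls) and by 0.19 with the 75th percentile. For 61.5% of genes the groups did not overlap, against 10% by chance.

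**Figure D2:**
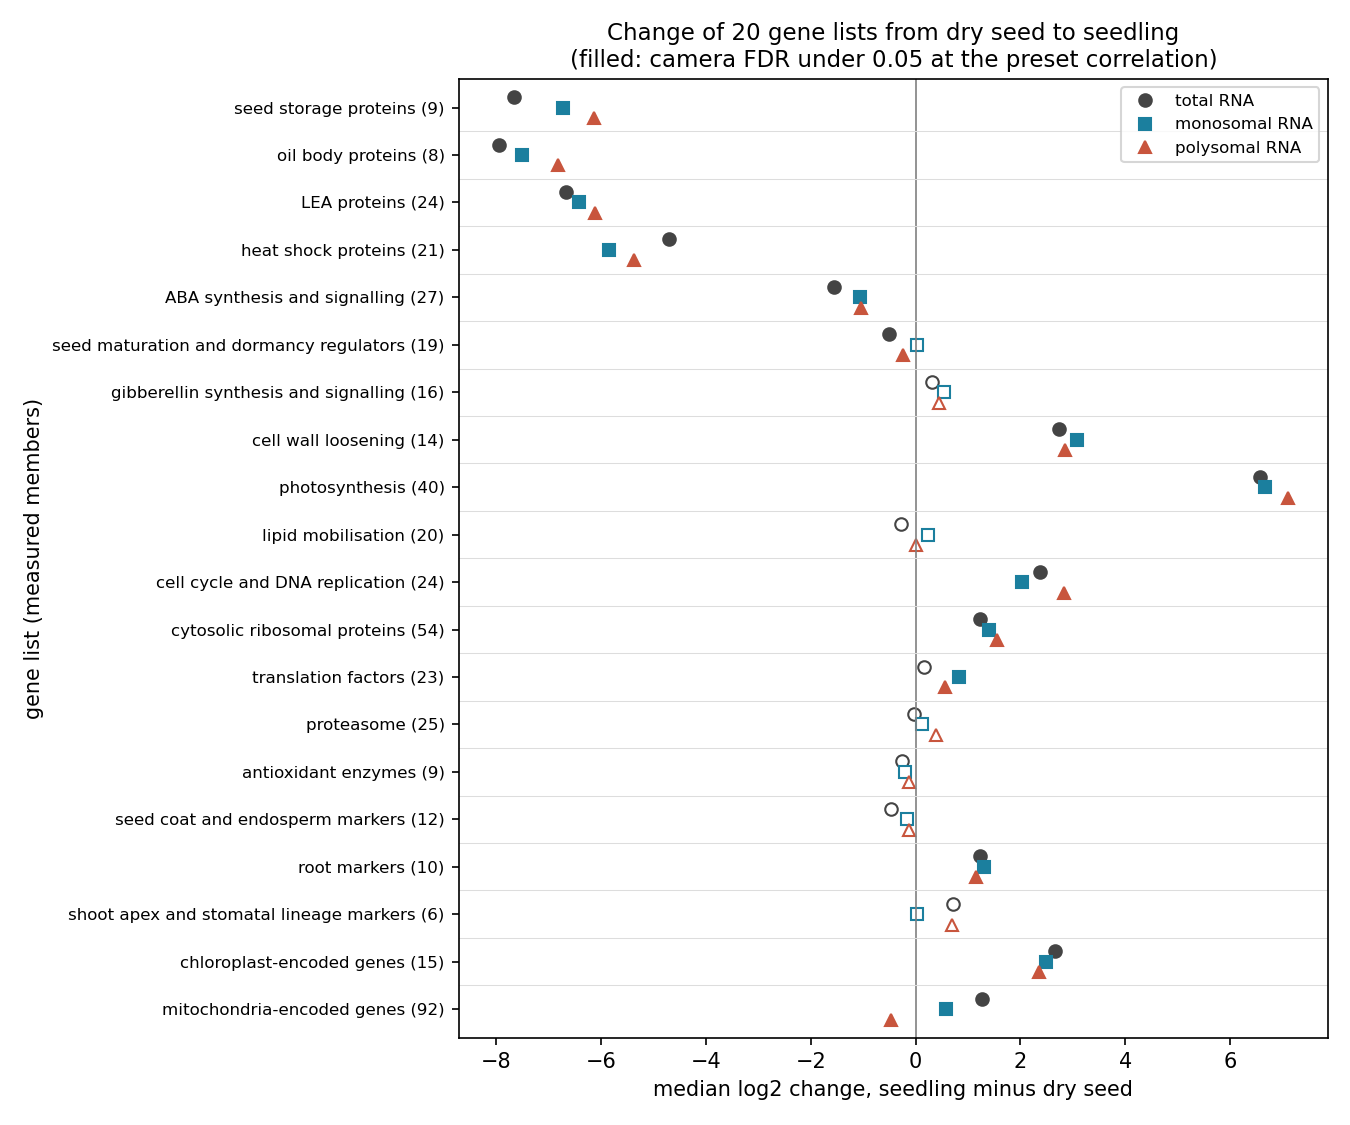
Median log2 change from dry seed to seedling of each of the 20 gene lists (vertical axis) in total, monosomal and polysomal RNA, with a filled mark where the set test passed an adjusted p of 0.05. Oil body, storage protein and LEA genes fell by more than 6 in every fraction and photosynthesis genes rose by more than 6, while lists close to 0 (gibberellin, translation factor, proteasome, maturation regulators, lipid mobilisation, antioxidant, seed coat, shoot apex) change direction under another array scaling in at least 1 fraction.

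Within dry seeds, monosomal was compared with total RNA to ask which stored transcripts sit with single ribosomes. Mitochondria-encoded transcripts were depleted, 61 of 92 lower and none higher (78 lower when adjusted over the list alone; median −1.09, adjusted p = 1.20e-50), for example ATMG00200 with 7.27 ± 0.06 in monosomal and 8.88 ± 0.08 in total RNA (change −1.60, SE 0.29, adjusted p = 0.00263). The metallothionein gene MT1C (AT1G07610) was higher in monosomal RNA, 7.24 ± 0.31 against 4.39 ± 0.62 (change 2.84, SE 0.33, adjusted p = 6.90e-05), and so was the ABA receptor gene PYR1 (AT4G17870), 7.92 ± 0.14 against 6.52 ± 0.12 (SE of the change 0.18, adjusted p = 0.000144). The largest rise was that of the long noncoding RNA AT2G23040 (change 3.05, SE 0.23, adjusted p = 7.91e-07). Among the largest falls were the noncoding RNA AT1G15405 (change −2.67, SE 0.26, adjusted p = 1.29e-05) and the small nucleolar RNA SNOR30 (AT5G51174, change −2.47, SE 0.29, adjusted p = 6.90e-05). Storage protein, oil body, seed maturation, cell wall, photosynthesis, cell cycle, seed coat, root and shoot apex lists had no gene past the threshold, and CRA1 (11.64 ± 0.10 against 11.71 ± 0.08, adjusted p = 0.978) and DOG1 (change 0.96, SE 0.29, adjusted p = 0.0572) did not pass it either, although DOG1 did with loess scaling (adjusted p = 0.0465). Such storage protein values lie near the top of the measured range, 12.74. The SE rested on a variance common to all groups, seedlings included. For CRA1 it was 0.74, against SDs of 0.10 and 0.08 in these dry seed groups. For OLEO1 it was 0.52, against SDs of 0.04 and 0.06, and its values did not overlap. For seed genes that vary between seedling arrays, a missing call within dry seeds therefore cannot show that the fractions were alike. Ribosomal protein genes were higher in 7 of 54 cases (10 when adjusted over the list alone; adjusted p = 1.08e-05, adjusted p = 0.380 with an estimated correlation). Heat shock genes were higher in 3 of 21 (adjusted p = 0.0334, adjusted p = 0.679 with an estimated correlation), with HSP18.2 (AT5G59720), AT5G37670 and AT1G59860. The LEA genes AT3G02480 and LEA14 (AT1G01470) were higher by 1.77 and 0.81. The set test was lower for lipid mobilisation (adjusted p = 0.000644, adjusted p = 0.597 with an estimated correlation), where only the lipase gene SDP1 (AT5G04040) passed. It was also lower for translation factors (2 lower; adjusted p = 0.0405, adjusted p = 0.380 with an estimated correlation), namely EIF4G (AT3G60240) and eIFiso4G1 (AT5G57870). Chloroplast-encoded genes were lower in 4 of 15 cases (adjusted p = 0.00131, adjusted p = 0.380 with an estimated correlation), namely ATCG00990, ATCG01140, ATCG00240 and ATCG00140. These 4 rows carry values identical to another row, so which locus they measure is uncertain. ATCG00990 and ATCG01140 had the same values, 6.77 in monosomal and 7.82 in total RNA, so the same signal was counted under both names. The gene calls of SDP1, EIF4G, eIFiso4G1 and ATCG00240 each ended in at least 3 of the 6 fits that left out 1 array. The translation factor call was lost with arrays centred on their medians (adjusted p = 0.0554) and with a replicate block (adjusted p = 0.0568). In all, 964 genes were higher and 763 lower, 504 and 300 by at least 2-fold. The groups did not overlap in 23.1% of genes, against 10% by chance. The number past the threshold was 944 without monosomal replicate 3, 968 without monosomal replicate 2 and 1000 without total replicate 2.

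Polysomal was compared with total RNA of dry seeds to ask which stored transcripts carry several ribosomes. Genes lower in polysomal RNA included the noncoding RNA AT1G15405, with 7.97 ± 0.33 against 11.39 ± 0.04 (change −3.42, SE 0.26, adjusted p = 5.85e-07) and the spliceosomal RNA U1.5 (AT1G08115), with 8.31 ± 0.51 against 10.63 ± 0.07 (change −2.31, SE 0.38, adjusted p = 0.00320). Genes higher included AT1G76810 (an eIF5B gene), by 1.59 (SE 0.26, adjusted p = 0.00283) and EIF4G, the scaffold of the cap-binding complex, from 7.44 ± 0.39 to 8.53 ± 0.12 (SE of the change 0.20, adjusted p = 0.00548). The largest rise was that of AT5G17900 (change 2.48, SE 0.40, adjusted p = 0.00264). CRA1, OLEO1, ABI5 and DOG1 did not pass the threshold (adjusted p = 0.902, 0.730, 0.696 and 0.515). For CRA1 and OLEO1 this cannot decide whether the fractions differed, because the variance took in the seedling arrays. Their SDs in seedling polysomal RNA were 1.89 and 1.74, against 0.10 and 0.13 in dry seed polysomal RNA. The SE of the change was 0.74 and 0.52. The values of OLEO1 did not overlap (change −0.34), while those of CRA1 did (change −0.18). Of 23 translation factor genes 5 were higher (6 when adjusted over the list alone; adjusted p = 0.00388, adjusted p = 0.309 with an estimated correlation), AT1G76810 and EIF4G with EIF3A (AT4G11420), LOS1 (AT1G56070) and EIF4A1 (AT3G13920), and the list median of 0.20 turned to −0.02 with the 75th percentile. Lipid mobilisation genes were shifted up with 1 passing (adjusted p = 0.00102, adjusted p = 0.766 with an estimated correlation). Photosynthesis genes were shifted down (adjusted p = 0.00388, adjusted p = 0.766 with an estimated correlation). Of 40 genes 2 passed (5 when adjusted over the list alone), LHCB2.2 (change −1.33) and LHCA3 (AT1G61520, change −0.84). Medians of this list lay near the array medians in both groups, so many of its values are near the background. In the maturation list HSI2 (AT2G30470), HSL1 (AT4G32010) and HUB1 (AT2G44950) were higher, with a list median of −0.15, a mean of 0.06 and adjusted p = 0.628. Mitochondria-encoded genes were higher in 7 cases and lower in 3 (median −0.06, mean 0.04, adjusted p = 0.628), with ATMG01000 higher by 1.24. The calls of SESA2 (AT4G27150, the 1 storage gene lower), LHCA3, HSI2, HSL1, HUB1, EIF3A and LOS1 each ended in at least 4 of the 6 fits that left out 1 array. In all, 877 genes were higher and 418 lower, 394 and 129 by at least 2-fold. The groups did not overlap in 32.1% of genes, against 10% by chance. These counts turned to 457 and 2220 with the 75th percentile, which moved the median change of −0.08 by −0.22, and to 370 and 391 with loess scaling. The number past the threshold was 188, 579 and 310 without polysomal replicate 1, 2 or 3 and 698 and 383 without total replicate 1 or 2.

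Polysomal was compared with monosomal RNA of dry seeds to ask which transcripts carry many rather than single ribosomes at this stage. BIG (AT3G02260), which encodes a very large protein of auxin transport, had 8.96 ± 0.16 in polysomal and 5.73 ± 0.38 in monosomal RNA (change 3.23, SE 0.20, adjusted p = 4.67e-08), and AT1G67120, which encodes the ribosome assembly protein midasin, was higher by 2.66 (SE 0.22, adjusted p = 6.69e-07). EIF4G was higher by 1.88 (SE 0.20, adjusted p = 6.84e-06). MT1C was lower in polysomal RNA (change −3.08, SE 0.33, adjusted p = 6.97e-06), as were the trypsin inhibitor gene TI2 (AT2G43520; change −2.93, SE 0.42, adjusted p = 0.000105) and PYR1 (change −1.54, SE 0.18, adjusted p = 1.44e-05). ATMG00960, a mitochondrial gene, was higher by 2.49 (SE 0.22, adjusted p = 8.87e-07), and 67 of 92 mitochondria-encoded genes were higher and none lower (median 1.1, adjusted p = 1.85e-31). Higher in polysomal RNA were also 13 of 20 lipid mobilisation genes (14 when adjusted over the list alone; adjusted p = 7.55e-08, adjusted p = 0.276 with an estimated correlation) and 11 of 23 translation factor genes with 2 lower (adjusted p = 7.14e-05). Ribosomal protein genes were lower in 12 of 54 cases (adjusted p = 8.58e-05, adjusted p = 0.285 with an estimated correlation), RPL23AA (AT2G39460, change −1.18) among them. LEA genes were lower in 3 of 24 (adjusted p = 0.0287, adjusted p = 0.722 with an estimated correlation), namely AT3G02480 (change −2.08), LEA14 (change −0.82) and SMP1 (AT3G12960), whose call ended in all 6 fits that left out 1 array. The LEA call was lost with the 75th percentile (adjusted p = 0.119). The maturation regulators HSI2, HSL1 and HUB1 were higher by 1.26, 1.12 and 0.97. Of the storage genes only SESA2 was lower (change −1.54), and CRA1, OLEO1, ABI5 and DOG1 did not pass the threshold (adjusted p = 0.928, 0.818, 0.261 and 0.143). For CRA1 and OLEO1 the variance again took in the seedling arrays, so the missing calls cannot show that these fractions were alike. DOG1, with a change of −0.63, was called lower with the 75th percentile (change −0.84, adjusted p = 0.0382) and with loess scaling (change −0.96, adjusted p = 0.0276). In all, 3211 genes were higher and 2084 lower, 1455 and 688 by at least 2-fold. The groups did not overlap in 40.3% of genes, against 10% by chance. The balance depended on scaling, with 2130 higher and 5047 lower with the 75th percentile, which moved the median change of −0.12 by −0.21, and 2096 and 2880 with loess scaling.

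In seedlings, monosomal was compared with total RNA. Mitochondria-encoded transcripts were depleted, 62 of 92 lower and 4 higher (median −1.56, adjusted p = 1.54e-28, adjusted p = 0.0732 with an estimated correlation), ATMG01250 with 3.82 ± 0.53 against 9.20 ± 0.15 (change −5.38, SE 0.32, adjusted p = 8.55e-10). GA3OX2 was lower, 4.21 ± 0.43 against 6.26 ± 0.22 (change −2.05, SE 0.38, adjusted p = 0.000720), and so were the stomatal lineage gene SPCH (AT5G53210; change −1.37, SE 0.30, adjusted p = 0.00243), the seed coat and endosperm list's EPR1 (AT2G27380; change −1.77, SE 0.33, adjusted p = 0.000663) and SYP111 (change −1.38, SE 0.23, adjusted p = 0.000221). The seed oil regulator gene WRI1 (AT3G54320) was higher by 1.53 (SE 0.26, adjusted p = 0.000324). The strongest differences were AT5G49560, higher by 2.81 (SE 0.33, adjusted p = 6.09e-06), and the short unnamed coding gene AT2G11778, which reached 7.51 ± 0.10 in total RNA (change −6.01, SE 0.24, adjusted p = 8.59e-12). Heat shock genes were lower in 6 of 21 cases (adjusted p = 0.0405, adjusted p = 0.813 with an estimated correlation and 0.195 with loess scaling), including AT2G29500 (change −2.35). Ribosomal protein genes were higher in 18 of 54 and lower in 2 (adjusted p = 0.0328, adjusted p = 0.813 with an estimated correlation), EMB3010 (AT5G10360) by 0.93. Of 24 cell cycle genes 7 were lower and 2 higher without a list call (adjusted p = 0.325), and the median of −0.06 turned to 0.11 with arrays centred on their medians. In all, 4790 genes were higher and 4048 lower, 1377 and 2016 by at least 2-fold. The groups did not overlap in 44.4% of genes, against 10% by chance. The median change of 0.11 moved by 0.17 with arrays centred on their medians (7759 higher, 3026 lower) and by 0.14 with the 75th percentile (6945 and 3163).

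Polysomal was compared with total RNA of seedlings to ask which transcripts were being translated. PKT3 (AT2G33150), the thiolase of fatty acid β-oxidation, was higher in polysomal RNA, 10.81 ± 0.17 against 9.24 ± 0.09 (change 1.57, SE 0.18, adjusted p = 5.04e-06), as were the proteasome gene PAE1 (AT1G53850; change 1.18, SE 0.19, adjusted p = 0.000197) and SNRK2.3 (AT5G66880), an ABA-activated kinase gene (change 1.37, SE 0.18, adjusted p = 2.14e-05). HAI1 (AT5G59220), a phosphatase gene of ABA signalling, was lower (change −1.73, SE 0.20, adjusted p = 7.61e-06), and so were EPR1 (change −2.23, SE 0.33, adjusted p = 8.95e-05) and AT2G01023, with 3.21 ± 0.53 against 9.69 ± 0.09 (change −6.48, SE 0.25, adjusted p = 3.22e-12). Mitochondria-encoded genes were lower in 62 of 92 cases and higher in 1 (median −1.52, adjusted p = 7.60e-36), ATMG00820 (change −4.70, SE 0.31, adjusted p = 3.16e-09). Lipid mobilisation genes were higher in 10 of 20 cases (14 when adjusted over the list alone; adjusted p = 6.15e-06, adjusted p = 0.289 with an estimated correlation). So were proteasome genes in 9 of 25 (13 when adjusted over the list alone; adjusted p = 0.000106, adjusted p = 0.264 with an estimated correlation) and translation factor genes in 7 of 23 (adjusted p = 0.00425, adjusted p = 0.202 with an estimated correlation). Chloroplast-encoded genes were lower in 5 of 15 cases (adjusted p = 0.00969, adjusted p = 0.379 with an estimated correlation), including ATCG00230 (change −1.52). The 2 LEA genes lower were AT5G44310 and LEA14, whose calls ended in at least 4 of the 6 fits that left out 1 array, yet the LEA median was 0.55 (adjusted p = 0.369) and turned to −0.23 without polysomal replicate 3, when the list was called lower (adjusted p = 0.0401). Storage protein and oil body medians turned from 0.82 and 0.72 to −0.33 and −0.26 without that array. The seed metallothionein gene AtMT4a (AT2G42000) and AT1G05510, higher by 2.44 and 2.11, had an SD of 1.96 and 1.97 in polysomal RNA. Without polysomal replicate 3 these differences were 1.31 and 0.98, and both calls were lost with only the groups of the comparison. In all, 2744 genes were higher and 2968 lower, 729 and 1679 by at least 2-fold, and 4056 and 2421 when arrays were centred on their medians, which moved the median change of 0.08 by 0.11. In 41.3% of genes the groups did not overlap against 10% by chance.

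Polysomal was compared with monosomal RNA of seedlings to ask which transcripts carry many rather than single ribosomes in growing tissue. Genes higher in polysomal RNA included SYP111, with 6.91 ± 0.15 in polysomal and 4.69 ± 0.37 in monosomal RNA (change 2.23, SE 0.23, adjusted p = 1.78e-05), the cytokinesis kinesin gene HIK (AT1G18370; change 2.29, SE 0.24, adjusted p = 1.78e-05) and the replication gene MCM6 (AT5G44635; change 1.61, SE 0.20, adjusted p = 7.26e-05). The proteasome gene PAA1 (AT5G35590) was higher by 1.12 (SE 0.16, adjusted p = 0.000189) and AT1G76810 by 1.80 (SE 0.26, adjusted p = 0.000186). Genes lower included EXT13 (AT5G35190), an extensin gene (change −2.59, SE 0.34, adjusted p = 0.000110) and EXPA7 (AT1G12560), a root hair expansin gene (change −1.23, SE 0.22, adjusted p = 0.000849), while of 10 root markers 2 were lower without a list call (adjusted p = 0.528). The ribosomal protein gene AT5G03850 (RPS28) was lower by 1.11 (SE 0.21, adjusted p = 0.00151). Higher lists were lipid mobilisation (6 of 20, 12 when adjusted over the list alone; adjusted p = 3.23e-05, adjusted p = 0.412 with an estimated correlation) and cell cycle (9 of 24; adjusted p = 0.000387, adjusted p = 0.0705 with an estimated correlation). The proteasome list (7 of 25; adjusted p = 0.000428, adjusted p = 0.359 with an estimated correlation) and translation factors (6 of 23 with 1 lower; adjusted p = 0.00138, adjusted p = 0.129 with an estimated correlation) were also higher. Heat shock genes were higher in 4 of 21 cases, HSP90.1 (AT5G52640) by 1.58 with AT2G29500, AT4G21870 and HSP70 (AT3G12580) (adjusted p = 0.00706, adjusted p = 0.427 with an estimated correlation). The call was lost without polysomal replicate 3 (adjusted p = 0.410) and with loess scaling (adjusted p = 0.0865). Without that array storage protein and LEA genes were called lower, with medians of −0.93 (adjusted p = 0.000280) and −0.72 (adjusted p = 0.000191) in place of −0.17 and 0.02, the latter also turning to −0.18 with the 75th percentile. The monosomal arrays in this comparison include replicate 1, on which LEA genes lay above the other two. Mitochondria-encoded genes were higher in 8 cases and lower in 7 without a list call, and their median of 0.03 turned to −0.18 with the 75th percentile. In all, 3047 genes were higher and 2274 lower, 1195 and 685 by at least 2-fold. The groups did not overlap in 35.1% of genes, against 10% by chance. These counts turned to 1907 and 5289 with the 75th percentile, which moved the median change of −0.10 by −0.21, and to 2564 and 2872 with arrays centred on their medians.

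**Figure D3:**
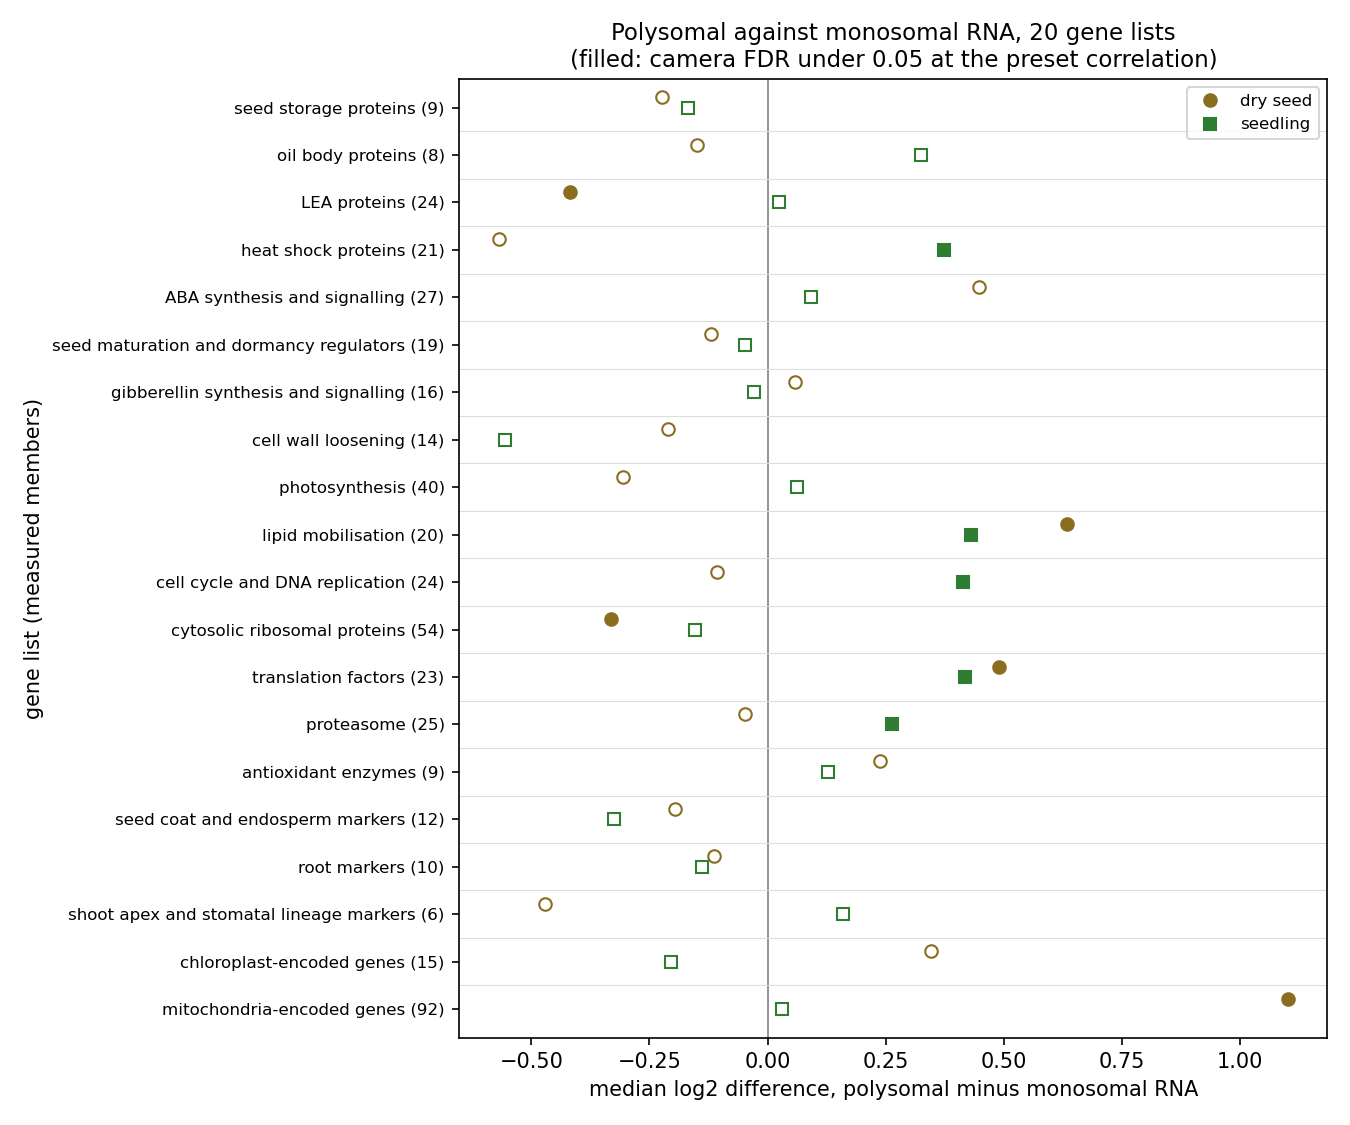
Median log2 difference between polysomal and monosomal RNA of each of the 20 gene lists (vertical axis) in dry seeds and in seedlings, with a filled mark where the set test passed an adjusted p of 0.05. Mitochondria-encoded genes lay at 1.1 in dry seeds and 0.03 in seedlings, and lists close to 0 (gibberellin and seed coat in dry seeds; LEA, ABA, photosynthesis, antioxidant, shoot apex and mitochondria-encoded in seedlings) change direction under another array scaling.

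The stage difference of monosomal against total RNA asked which transcripts are held with single ribosomes differently in dry seeds and seedlings. A positive value means that a transcript's monosomal against total difference, relative to other transcripts, was higher in seedlings than in dry seeds. It does not give the part of a transcript's molecules on single ribosomes. The small heat shock gene AT2G29500 had −2.71 (SE 0.31, adjusted p = 1.64e-05), from 10.94 ± 0.04 against 10.59 ± 0.05 in dry seeds and 5.09 ± 0.23 against 7.44 ± 0.18 in seedlings. GA3OX2 had −2.30 (SE 0.54, adjusted p = 0.00728) and PYR1 −1.35 (SE 0.25, adjusted p = 0.00134). LEC1 (AT1G21970), an embryo regulator, had 1.42 (SE 0.27, adjusted p = 0.00146), with means of 2.45 ± 0.23 and 1.23 ± 0.19 in seedlings that lie near the lower end of the values. The largest positive value was that of AT1G62620 (3.90, SE 0.85, adjusted p = 0.00424) and the largest negative that of AT2G11778 (−6.22, SE 0.33, adjusted p = 2.72e-09). Heat shock genes were lower in 5 of 21 cases (median −0.75, adjusted p = 0.00282), mitochondria-encoded genes lower in 35 and higher in 21 (median −0.32, adjusted p = 0.00366) and lipid mobilisation genes higher in 3 of 20 (median 0.45, adjusted p = 0.0258), namely CSY2 (AT3G58750), PKT3 and CSY3 (AT2G42790), whose calls each ended in at least 2 of the 12 fits that left out 1 array. All of these list calls were lost, each at adjusted p = 0.907 with an estimated correlation, and the lipid call also with loess scaling (adjusted p = 0.0758). Seedling medians of the heat shock list, 2.86 to 3.15 in monosomal and 3.64 to 3.75 in total RNA, lay near or under the array medians. In all, 2580 genes were higher and 2740 lower, 1903 and 2365 by at least 2-fold. These counts were 4034 and 2177 when arrays were centred on their medians and 3837 and 2149 with the 75th percentile. Both scalings moved the median of 0.12 by 0.15.

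The same difference for polysomal against total RNA asked which transcripts change in polysomal relative to total RNA. ATMG01250 had −4.93 (SE 0.45, adjusted p = 1.57e-06), from 6.99 ± 0.17 against 6.66 ± 0.17 in dry seeds and 4.60 ± 0.75 against 9.20 ± 0.15 in seedlings, and 55 of 92 mitochondria-encoded genes were lower with none higher (median −1.39, adjusted p = 6.30e-38). LHCB2.2 had 1.69 (SE 0.29, adjusted p = 0.00132), PAE1 1.44 (SE 0.27, adjusted p = 0.00224), PKT3 1.16 (SE 0.25, adjusted p = 0.00833) and HAI1 −1.58 (SE 0.29, adjusted p = 0.00218). The plastid fatty acid binding protein gene FAP3 (AT1G53520) had 2.49 (SE 0.39, adjusted p = 0.000522). Its dry seed means, 1.46 in polysomal and 2.50 in total RNA, lie near the background. The largest negative value was that of AT3G50250 (−6.50, SE 0.61, adjusted p = 1.63e-06). Photosynthesis genes were higher in 6 of 40 cases (median 0.51, adjusted p = 0.00235, adjusted p = 0.738 with an estimated correlation). Dry seed medians of this list lay near the array medians, 2.82 to 3.16 in polysomal and 2.90 to 3.76 in total RNA. The dry seed part of this stage difference thus rests in many genes on values near the background. Proteasome genes were higher in 3 of 25 (PAE1, PAB1 and RPN10; median 0.45, adjusted p = 0.00235, adjusted p = 0.530 with an estimated correlation). Cell cycle genes were higher in 4 of 24 (CDKB2;2, CDKB1;1, SYP111 and MCM2; median 0.41, adjusted p = 0.0478, adjusted p = 0.418 with an estimated correlation). Dry seed values of these 4 genes, 1.85 to 3.33 on average, lie near the background, and their calls each ended in at least 6 of the 12 fits that left out 1 array. The cell cycle list call was lost with the 75th percentile (adjusted p = 0.0559). In all, 1124 genes were higher and 1380 lower, 922 and 1280 by at least 2-fold. They were 1486 and 1196 when arrays were centred on their medians and 2075 and 1066 with the 75th percentile, which moved the median of 0.10 by 0.15. The number past the threshold fell from 2504 to 1530 without dry seed polysomal replicate 1 and to 1594 without dry seed polysomal replicate 3.

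For polysomal against monosomal RNA, SYP111 had a stage difference of 2.25 (SE 0.32, adjusted p = 0.000531), from 1.85 ± 0.13 against 1.87 ± 0.27 in dry seeds and 6.91 ± 0.15 against 4.69 ± 0.37 in seedlings. MCM6 had 1.69 (SE 0.28, adjusted p = 0.00131). The dry seed values of both genes lie near the background, as do the medians of the cell cycle list, so these stage differences largely restate those within seedlings. Further values were those of AT2G29500 (2.18, SE 0.31, adjusted p = 0.000508) and the ABA-activated kinase gene OST1 (AT4G33950; 1.46, SE 0.28, adjusted p = 0.00319). EIF4G had −1.46 (SE 0.28, adjusted p = 0.00301), while EIF4E (AT4G18040), the cap-binding protein gene, had 1.75 (SE 0.33, adjusted p = 0.00249). TI2 had the largest value (3.51, SE 0.60, adjusted p = 0.00146) and AT3G50250 the lowest (−3.98, SE 0.61, adjusted p = 0.000752). Mitochondria-encoded genes were lower in 46 of 92 cases and higher in 1 (median −1.13, adjusted p = 9.74e-23, adjusted p = 0.0755 with an estimated correlation), including ATMG00570 (change −2.52). Heat shock genes were higher in 8 of 21 cases (median 0.73, adjusted p = 4.77e-05, adjusted p = 0.316 with an estimated correlation). Seedling medians of this list were 2.86 to 3.15 in monosomal and 2.88 to 4.12 in polysomal RNA. They lay under the array medians except on polysomal replicate 3, so the seedling part rests in many genes on values near the background. Cell cycle genes were higher in 8 of 24 with 1 lower (median 0.71, adjusted p = 0.000699, adjusted p = 0.0755 with an estimated correlation) and proteasome genes in 4 of 25 (PAE1, PAD1, PAA1 and PAG1; adjusted p = 0.00652, adjusted p = 0.445 with an estimated correlation). Photosynthesis genes were higher in 2 of 40 cases, LHCB2.2 and LHCA2 (adjusted p = 0.0353, adjusted p = 0.699 with an estimated correlation), a list call lost without seedling polysomal replicate 3 (adjusted p = 0.0581) and with loess scaling (adjusted p = 0.0831). Dry seed medians of this list lay near the array medians in both fractions. Gene calls of PAD1, PAG1, LHCB2.2 and LHCA2 each ended in at least 1 of the 12 fits that left out 1 array. In all, 1584 genes were higher and 1335 lower, 1361 and 1129 by at least 2-fold. This balance turned with arrays centred on their medians (1295 higher, 1588 lower), while loess scaling gave 1832 and 1148. The number past the threshold fell from 2919 to 1835 without dry seed polysomal replicate 2.

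The last comparison asked whether transcripts enriched on single ribosomes in dry seeds are those enriched on polysomes of seedlings. Of 964 genes higher in dry seed monosomal than total RNA and 2744 higher in seedling polysomal than total RNA, 108 were shared, against 95.1 by chance (odds ratio 1.16, Fisher's exact test, two-sided p = 0.153, adjusted p = 0.163 over 16 overlaps). This result depended on the settings. With trend and robust variance 161 were shared against 131.8 by chance (Fisher's exact p = 0.00720). Fewer than by chance were shared without the dimmer genes, down to the middle of the range (186 against 227, Fisher's exact p = 0.00142), and with only the groups of each comparison (25 against 38.4, Fisher's exact p = 0.0204). Shared genes, named after their values were seen, included MES1 (AT2G23620), a methyl jasmonate and salicylate esterase gene, with 1.48 (SE 0.34) in dry seeds and 1.11 (SE 0.34) in seedlings, and AT5G17900, with 2.03 (SE 0.40) and 1.52 (SE 0.40). Of the 20 gene lists only the antioxidant list had a shared gene, CSD1 (AT1G08830), a cytosolic superoxide dismutase. Genes lower in both comparisons numbered 134 against 81.4 by chance (adjusted p = 1.08e-08). Genes lower in dry monosomal RNA but higher in seedling polysomal RNA numbered 123 against 75.2 by chance (adjusted p = 7.57e-08). In contrast, 920 genes were higher in polysomal than monosomal RNA at both stages, against 351.6 by chance (adjusted p = 3.31e-196), and 400 were lower at both against 170.3 (adjusted p = 5.27e-62). Fisher's exact test takes genes as independent, which they are not, so none of these p-values measures variation between replicates. The number by chance also takes every gene as equally likely to be called. Both comparisons used the same variance estimate of each gene, so genes with a small variance can be called in both. The 134 and 123 genes, above chance in both directions, therefore cannot show that the fractions are linked. For 920 and 400 the opposite directions lay below chance, with 85 against 262.4 and 181 against 228.2. The overlaps of 920 and 400 genes are given at the main settings only. The shared number of 108 fell to 65 (56.3 by chance) and 63 (53.3) without dry seed monosomal replicate 2 or 3 and to 69 (63.8) and 59 (53.1) without dry seed total replicate 1 or 2. It fell to 70 (67.1) and 56 (70.7) without seedling polysomal replicate 1 or 3 and to 56 (55.7) and 49 (57.8) without seedling total replicate 1 or 2. Without seedling polysomal replicate 2 it was 85 against 65.8 by chance (Fisher's exact p = 0.0159).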

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

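Tests of protein size, of nuclear copies of mitochondrial genes and of other splits of the arrays were written before their results were seen, and all other tests in this part were chosen only after the result was seen. The comparisons, gene lists and alternatives were fixed before the data were examined, except for the set test without seedling polysomal replicate 3.

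Seed transcripts on seedling polysomal replicate 3 were consistent with RNA of dry or ungerminated seed in that sample. The pattern was seen in the gene lists, so their members were left out of its test. Of 65 other genes at 10 or more on dry polysomal and under 5 on seedling total arrays, 64 were highest on replicate 3, 1 on replicate 1 and 0 on replicate 2. They lay above the other two by a median log2 difference of 2.96, and the added signal had a median of 2.80% of the dry level. On the seedling monosomal arrays 38, 9 and 18 of them were highest on replicates 1, 2 and 3, with medians of 3.58, 2.93 and 3.16, so replicate 1 was raised to a lesser degree. Against scaling of polysomal replicate 3 as the cause, the 65 genes lay 3.056 above the other two after loess scaling (interquartile range 2.23 to 3.54), which moved no gene by more than 0.0983. Less advanced seedlings would have less photosynthesis RNA, whereas that list lay 0.0801 above the other 2 polysomal arrays. This speaks only against a delay of the whole sample. A small share of delayed seedlings would hardly move that list and stays open. The source of the seed RNA was not tested, and no other biological explanation was tested.

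The negative stage difference of mitochondria-encoded transcripts in polysomal against total RNA (median −1.39) was not explained by array scaling or by identical rows alone. From dry seed to seedling the list median changed by 1.27 in total and by −0.47 in polysomal RNA. Within seedlings the list was also lower in monosomal than total RNA (median −1.56). Relative to all genes the list had −1.4812 with loess scaling, while centring of arrays moves all genes alike and tests nothing here. Members without an identical row had −0.9294. The grouping of probes was not given, so rows sharing only some probes with a nuclear copy could not be left out. Partly shared probes therefore stay open. Small nuclear and nucleolar RNAs had a median of −1.272 in dry polysomal against total RNA, with 6 of 13 past the threshold. As a set, the signals of these nuclear RNAs were thus lower in dry polysomal than in total RNA. How fully the 3' labelling covers such RNAs was not tested. These signals cannot show whether cytosolic particles or organelles without polysomes were in the polysomal fraction. Mitochondria or their polysomes sedimenting with the polysomal fraction of dry seeds could give this pattern and were not tested. A biological change of mitochondrial RNA between the stages also stays open.

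On the seedling total arrays alone, 64 transcripts lay at least 2 above all other 15 arrays, against at most 1 in any other group. After loess scaling, which moved single genes by up to 0.59, 52 of the 64 still did, which argues against scaling as the cause for these 52, and for the other 12 it stays open. Mitochondrial sequence, encoded or as a nuclear copy, accounted for 22 of them and left 42, among them AT2G11778 (7.51 against a mean of 1.51 elsewhere) and AT2G01023 (9.69 against 4.09). RNA that is not bound by ribosomes in seedlings may be among the causes and was not tested, and no biological explanation was tested.

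The following genes and lists passed the test of the difference between dry seeds and seedlings, the lists at the preset correlation. The stage difference of monosomal against total RNA held 5320 genes. Among them AT1G62620 had 3.90, LCR40 2.70, AT3G63052 2.68, UBQ12 2.64 and ABCC9 2.63. At the other end AT2G11778 had −6.22, AT4G08370 −6.12, AT1G34910 −5.86, AT5G66564 −5.54 and AT4G18690 −5.43. List medians were −0.75 for heat shock, 0.45 for lipid mobilisation and −0.32 for mitochondria-encoded genes, of which 35 were lower and 21 higher. Each of these 3 list calls was lost with an estimated correlation (adjusted p = 0.907), and lipid mobilisation also with loess scaling (adjusted p = 0.0758). Seedling medians of the heat shock list lay near or under the array medians.

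For polysomal against total RNA 2504 genes differed between stages. AtMT4a had 2.92, UBQ12 2.74, AT3G45851 2.51, FAP3 2.49 and SUC9 2.46. The value of AtMT4a fell to 1.79 without seedling polysomal replicate 3. Its call was lost without dry seed polysomal replicate 1 (2.91) or 3 (2.85) or seedling total replicate 1 (2.70) and with trend and robust variance. All group means of AT3G45851 and SUC9, and those of FAP3 in dry seeds, lay under the array medians, near the background. The highest mean of UBQ12 was 3.98, in dry seed total RNA. Negative values were −6.50 for AT3G50250, −5.97 for AT2G11778, −5.90 for AT4G08370, −5.83 for AT2G01023 and −5.16 for AT4G18690. List medians were 0.51 for photosynthesis, 0.41 for cell cycle, 0.45 for proteasome and −1.39 for mitochondria-encoded genes. In dry seeds the photosynthesis and cell cycle lists had values near or under the array medians. With an estimated correlation the mitochondrial call held (adjusted p = 0.0266) and the others were lost (adjusted p = 0.738, 0.418 and 0.530), cell cycle also with the 75th percentile (adjusted p = 0.0559).

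For polysomal against monosomal RNA 2919 genes differed. TI2 had 3.51, AT5G39730 3.50, AT5G53410 3.27, CHUP1 2.87 and AT1G01390 2.85, while AT3G50250 had −3.98, BGLU3 −2.91, NAXT1 −2.85, AT4G38780 −2.83 and AT5G13230 −2.71. List medians were 0.73 for heat shock, 0.32 for photosynthesis, 0.71 for cell cycle, 0.36 for proteasome and −1.13 for mitochondria-encoded genes. The photosynthesis and cell cycle lists again had dry seed values near or under the array medians. All 5 list calls were lost with an estimated correlation (adjusted p = 0.316, 0.699, 0.0755, 0.445 and 0.0755). Photosynthesis was also lost without seedling polysomal replicate 3 (adjusted p = 0.0581) and with loess scaling (adjusted p = 0.0831).

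The arrays were regrouped to see how many genes other splits call. For comparisons of 3 against 3 arrays there are only 10 splits, so the lowest possible share is 0.1 and the splits are too few, with only the real split (1 of 10) calling as many genes in each comparison. Between stages the real split called 17294, 14365 and 14907 genes for total, monosomal and polysomal RNA, and the highest other 0, 1 and 0. In dry seeds it called 1727, 1295 and 5295 for monosomal against total, polysomal against total and polysomal against monosomal RNA, and the highest other 1, 0 and 0. In seedlings these were 8838, 5712 and 5321, and 0, 2 and 20. For the stage differences 2 of 100 splits called as many genes, the real split and the split with the fraction labels of a single stage turned, which was singled out after its result was seen. The real splits called 5320, 2504 and 2919 and the turned ones 5725, 5572 and 7912, while the highest of the other 98 were 4063, 2271 and 1335. A turned split adds the fraction differences that both stages share, so its larger counts do not bear on chance. The other splits break up these shared differences as well. The counts therefore cannot decide whether chance gave the stage differences.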

How the results depend on the processing

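No test in this part was chosen only after the result was seen, except the set test without seedling polysomal replicate 3. With 3 arrays per group, a log2 scale compressed at both ends and no detection calls, genes near the background of the arrays cannot be told from absent ones, and calls depend on the spread of few arrays. There was 1 row per gene, so taking all rows not controls or the mean of features changed nothing. The cause was not tested for any change listed here.

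Without the dimmest genes, down to the middle of the range, total RNA between stages had 10831 calls, seedling monosomal against total RNA 4992, the stage difference of polysomal against total RNA 1496 and the overlap 186 against 227 by chance (Fisher's exact p = 0.00142), a reversed direction. A 2-fold change left 11445 for total RNA between stages. In dry seeds it left 804 for monosomal against total, 523 for polysomal against total and 2143 for polysomal against monosomal RNA. In seedlings it left 3393, 2408 and 1880, and 16 in the overlap. An adjusted p under 0.01 left 673, 183 and 2789 in dry seeds, 4676, 2958 and 2315 in seedlings, 2052, 792 and 1054 for the stage differences in the same order of fractions, and 19 in the overlap. With only the groups of a comparison, dry seed monosomal against total RNA had 623 calls, seedling polysomal against monosomal RNA 2299 and the overlap 25 against 38.4 by chance (Fisher's exact p = 0.0204), also reversed. Dry seed polysomal against total RNA had 2677 calls with the 75th percentile, 761 with loess scaling and 2840 with array weights, and array weights gave 4070 for its stage difference. With trend and robust variance the overlap was 161 against 131.8 by chance (Fisher's exact p = 0.00720). ACT7 in total RNA between stages turned from 0.48 to −0.0232 with arrays centred on their medians, and ICL in polysomal RNA from 0.66 to −0.22 with loess scaling.

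Leaving out 1 array at a time gave 944 to 1713 calls for dry seed monosomal against total RNA, 188 to 1196 for dry seed polysomal against total RNA, 1530 to 2490 for the stage difference of polysomal against total RNA, 1835 to 2855 for that of polysomal against monosomal RNA, and 49 to 85 genes for the overlap. For dry seed polysomal against total RNA the count was 188 without polysomal replicate 1, 579 without replicate 2, 310 without replicate 3, 698 without total replicate 1 and 383 without total replicate 2. Without seedling polysomal replicate 3, LEA genes were lower in seedling polysomal than total RNA (adjusted p = 0.0401), and storage protein (adjusted p = 0.000280) and LEA genes (adjusted p = 0.000191) were lower in polysomal than monosomal RNA. The same setting also gave calls for heat shock (adjusted p = 0.0401) and cell cycle genes (adjusted p = 0.0135) in polysomal against total RNA and for ribosomal protein genes (adjusted p = 0.0410) in polysomal against monosomal RNA. Under the other settings p ranged from 0.301 to 0.829 for LEA genes against total RNA, and from 0.663 to 0.997 for storage protein and LEA genes against monosomal RNA.

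With a replicate block, calls between stages were 17256 for total, 14373 for monosomal and 14867 for polysomal RNA. Within dry seeds they were 1634, 1024 and 5139 and within seedlings 8762, 5657 and 5197 for monosomal against total, polysomal against total and polysomal against monosomal RNA, and for the stage differences 5197, 2369 and 2722, with an overlap of 94. Each of these counts lay within 1.5 times the reported one. Same-number arrays of different groups correlated between −0.058 and 0.078 after group means were removed. Within stages 14 of 18 arrays correlated best with arrays of their own number, a hint from the data and not the design that numbers may follow blocks. Of 79 list calls 51 were lost with an estimated correlation and 0 gained. Loess scaling lost 5 and gained 13, the 75th percentile lost 2 and gained 2, arrays centred on their medians lost 2 and gained 1, and a replicate block lost 1 and gained 3. Of 761 calls of named genes 92 were lost with only the groups of a comparison, 47 with loess scaling, 37 with either other scaling, 26 with array weights and 21 with trend and robust variance or a replicate block.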

Other observations

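The tests in this part were written before their results were seen, and none was chosen only after the result was seen, while the genes named here were chosen after their values were seen. In dry seeds, genes of large proteins were shifted towards polysomal and genes of small proteins towards monosomal RNA, relative to other genes. Of 27 genes of large proteins 25 were higher in polysomal than monosomal RNA (median 1.69, interquartile range 1.37 to 1.84, set test p = 5.45e-29, p = 0.000624 with an estimated correlation), among them the kinase genes TOR with 2.05 and ATM with 2.33. Of 25 genes of small proteins 17 were lower (median −0.81, interquartile range −1.0 to −0.52, set test p = 4.26e-11, p = 0.00779 with an estimated correlation), among them the histone gene HIS4 with −1.44 and the polymerase subunit gene NRPB10 with −1.87. The difference of 2.4945 between the medians was 2.3628 with loess scaling, while centring of arrays cannot change it, and is consistent with long coding sequences holding more ribosomes.

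In seedlings the same contrast had the same direction, and its difference from dry seeds was not tested. Of large proteins 12 were higher (median 0.56, interquartile range 0.37 to 0.91, p = 1.36e-09, p = 0.0286 with an estimated correlation), and of small proteins 11 were lower and 2 higher (median −0.49, interquartile range −0.69 to −0.15, p = 0.000874, p = 0.134 with an estimated correlation). HIS4 and SAD1, lower in dry seed polysomal RNA, were higher by 0.83 and 1.04 in seedlings. The difference of 1.0501 in seedlings (0.8851 with loess scaling) is in line with the same reading, and the genes that differ between polysomal and monosomal RNA at both stages may therefore reflect coding length in part. Ribosome density per transcript was not measured, and gene length itself was not used here.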
